A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

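Ribosome profiling (Ribo-seq), which sequences the RNA fragments that ribosomes shield from nuclease, was performed on budding yeast (*Saccharomyces cerevisiae*, strain background BY4741). Wild-type (WT) cells and cells carrying a upf1 mutation were compared. Upf1 is an RNA helicase required for nonsense-mediated decay (NMD), the pathway that degrades RNAs whose translation ends prematurely. Per the labels' protocols, cells were grown in YPD at 30 °C to an OD600 of 0.5, and cells were left untreated or received cycloheximide (CHX), an inhibitor of translation elongation, for 15 min. Per the same protocols, 250 ml of cells were harvested per sample, polysomes were purified on a sucrose cushion and digested with RNase I at 5 units per A260, rRNA was depleted, and small-RNA libraries were made from 10 ng of protected RNA. The labels describe 8 libraries in 4 conditions, with 2 biological replicates each.

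The data analysed here were 1 table of open reading frames (ORFs) in Xrn1-sensitive unstable transcripts (XUTs), long noncoding RNAs that accumulate without the cytoplasmic exonuclease Xrn1. For each ORF the authors deposited a read count and a phase score in every condition, plus a pooled count and a pooled score over all conditions. The deposited counts were whole numbers that were not scaled to library size. The deposited score ran from 0 to 1. Per the submitters' processing notes, UMI-tools, cutadapt and HISAT2 2.2.0 were used with the genome build R64. The tool that listed the ORFs and scored them, its read-length and offset settings, and the way replicates were merged are not given in the sources used here. The pooled count equalled the sum of the 4 conditions for 98.5% of the ORFs, and the largest difference was 13 reads.

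Because the table holds 1 value per ORF and condition, no spread between replicates could be computed. No p-value is therefore given for a difference between conditions, and the planned tests for ORFs changed between conditions (edgeR, or limma on scores) were not run. Intervals are 95% intervals. Those on shares are exact (Clopper-Pearson) binomial intervals, those on medians come from order statistics over ORFs, and those on ratios come from 1000 bootstrap draws over transcripts. All of them cover counting error or variation over ORFs and transcripts, not variation between cultures. The column sums cover XUT ORFs only and are not library depths, so levels were compared between conditions only as shares of the reads in these ORFs.

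Coordinates are 1-based on R64 and end before the stop codon. In the R64 sequence all 13912 ORFs on nuclear and mitochondrial chromosomes began with ATG and were followed by a stop codon. The 29 ORFs on the 2-micron plasmid were not compared with a reference sequence. Each ORF was assigned to a coding sequence (CDS) on the same or the opposite strand if they overlapped by at least 1 nt. XUT boundaries were not used here, so position along a transcript, planned as a fraction of its length, is the order of its listed ORFs from the 5′ end, scaled from 0 for the first to 1 for the last. Of the listed ORFs, 60.8% overlapped another listed ORF on the same strand and could share its reads. A set of 9205 non-overlapping ORFs, taken in order of pooled count, was used for sums per transcript.

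An ORF was called translated at a phase score of at least 0.32, a threshold set before the data were examined together with the comparisons, the gene lists and the rule for named ORFs. The file carried no status column of its own. Most deposited scores of ORFs with few reads took the values of the mean resultant length of codon phase vectors, in which a single read gives 1. That formula was inferred and left some scores unexplained: of the ORFs with 1 read, 90.4% in WT, 88.4% in WT + CHX, 91.3% in upf1 and 89.2% in upf1 + CHX scored 1 and the rest scored 0. The simulated background is therefore too high at 1 read. A background was simulated with that formula by placing each ORF's reads independently and evenly over its length, without any frame, 200 times per ORF. It does not model reads piled up on few codons. Such ORFs occur, for example 24 reads scoring 0 in a 162-nt ORF of XUT0387 in WT + CHX. A score or score difference beyond this background therefore need not come from framing. On simulated data for the 949 ORFs with at least 10 reads in upf1 + CHX, with 200 of them given 80% of reads in frame, 99% of the framed ORFs and 26.4% of the frameless ones were called. In the same simulation 198 frameless calls were observed against 219 predicted. A simulated 2-fold ratio of antisense to other reads over 13941 ORFs came back as 1.96. Random calls in 300 transcripts gave a position-test p under 0.05 in 2 of 40 sets.

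The score difference of a contrast was the median over ORFs with reads in both conditions. Position was tested by permuting calls within transcripts (100000 permutations, 10000 per condition, two-sided). Sequence context was tested with two-sided Fisher's exact tests across ORFs and Benjamini-Hochberg adjustment over 15 tests. ORFs and transcripts are not independent replicates. Named ORFs were, per contrast, the 8 largest rises and 8 largest falls in score with at least 10 reads in both conditions and a call in at least 1, with at most 1 ORF per transcript. The rule also named the 10 transcripts with the highest mean score, the 5 with most called ORFs, up to 4 members per gene list and XUT0741, an example used in the study. Those with the largest change in read share, those with most reads and the pseudogenes were chosen after their values were seen, as were all settings with a minimum of 10 reads other than the count of called ORFs and the rule for named ORFs. For genomic context only the overlap with genes was planned. The read shares and ratios by genomic context, first ORF and ORF length, the comparison with frameless reads and the position tests at matched depth were also chosen after the data were examined. ORFs of the 2-micron plasmid were left out of the analyses of position, first ORFs and reads by ORF length, except where they are said to be kept. Transcript shares were compared where the summed reads were at least 30 and each condition had at least 4. Shares of transcripts and pseudogenes are of all reads in non-overlapping ORFs, with the 2-micron plasmid kept. The plasmid held 25.4% of those reads in WT, 6.55% in WT + CHX, 10.9% in upf1 and 5.70% in upf1 + CHX. Without it, every ratio against untreated WT would be smaller.

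The gene lists were matched by the gene on the opposite strand and covered cytosolic ribosomal proteins, glycolysis, NMD targets and mRNAs with upstream ORFs, histones, phosphate, galactose, amino acid synthesis, heat shock and stress, cell cycle and mating, sporulation, and transporters. Lists of other RNA classes (CUT, SUT and other noncoding RNAs) had no members in the table. List medians were placed among 10000 random lists matched on mean score. Alternatives covered the score threshold (0.25, 0.3, 0.4, 0.43 and 0.5), ORF length (30 and 60 nt), read minimum (10 and 30), 1 ORF per transcript, the ORFs entering a median, the measure of position and the comparison ORFs of the sequence context. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used Matplotlib 3.10.9. No ORF lay in or opposite UPF1 (NAM7), so the genotype labels could not be checked from these values.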

Results

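Ribosome footprints were examined in 13941 ORFs of 1637 XUTs in 4 conditions: WT, WT + CHX, upf1 and upf1 + CHX. Each condition had 2 biological replicates, which the table merges into 1 value, so no value below has a replicate error. The ORFs were 15 to 4038 nt long with a median of 48 nt, and a transcript held a median of 6. Of the ORFs, 7931 in 1084 XUTs lay antisense to a CDS of 1075 genes and 5931 overlapped no CDS. A further 50 overlapped a CDS or pseudogene on their own strand, and 29 lay on the 2-micron plasmid. The XUT ORFs held 5897 reads in WT, 35728 in WT + CHX, 26791 in upf1 and 44035 in upf1 + CHX.

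The first question was in which XUT ORFs the reads keep to 1 frame. By the inferred formula any frame can give a high score, so a call does not show that the ORF's own frame was read. With at least 10 reads in the same condition, 963 ORFs of 527 XUTs, or 32.2% of the XUTs, were called translated in at least 1 condition. ORFs with 10 reads in more conditions could be called in more of them. No background was computed for this union, so it is no estimate of the share of XUTs translated. By condition the called ORFs were 41 in WT, 517 in WT + CHX, 317 in upf1 and 689 in upf1 + CHX. Of these, 29, 319, 228 and 457 overlapped another listed ORF and could be called from its reads. The called share of ORFs at that depth was 70.7% (95% exact interval 57.3 to 81.9) in WT, 64.2% (60.8 to 67.5) in WT + CHX, 62.9% (58.5 to 67.1) in upf1 and 72.6% (69.6 to 75.4) in upf1 + CHX. Reads placed evenly without a frame gave 27.6%, 30.0%, 27.6% and 28.9%, or 16, 241, 139 and 274 calls. The calls lay above that background in every condition. Because it leaves out reads piled up on few codons, the excess cannot be read as framing alone. With no read minimum, the setting fixed in advance, 1746 ORFs (12.5% of all, 11.98 to 13.1) were called in WT, 4646 (33.3%, 32.5 to 34.1) in WT + CHX, 4356 (31.2%, 30.5 to 32.0) in upf1 and 5012 (36.0%, 35.2 to 36.8) in upf1 + CHX. Most of those calls rested on 1 or 2 reads, 81.7% (79.8 to 83.5) of them in WT and 57.8% (56.4 to 59.2) in upf1 + CHX. Simulated frameless ORFs with 1 or 2 reads always passed the threshold.

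**Figure D1:**
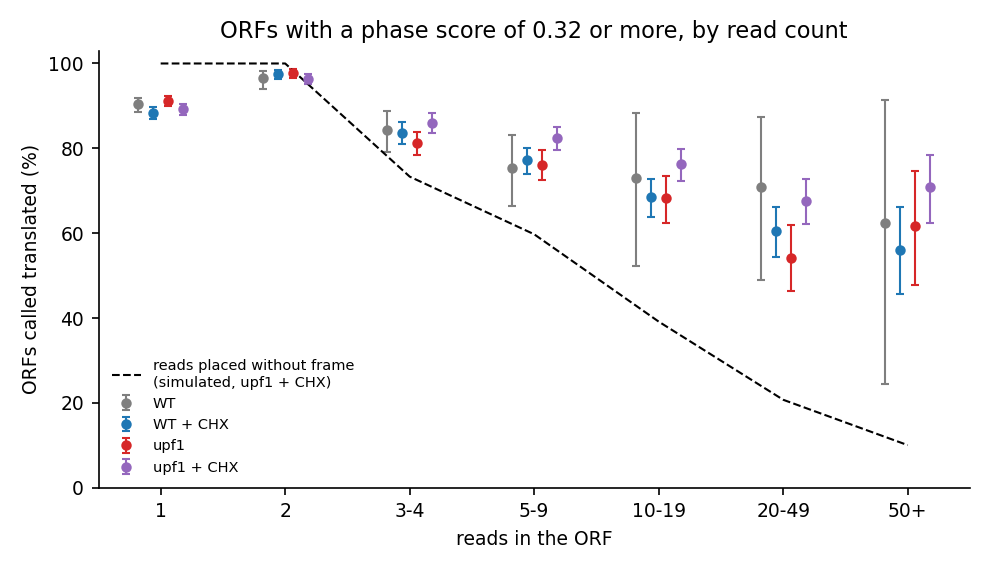
Share of ORFs with a phase score of 0.32 or more (vertical axis, percent) by number of reads in the ORF (horizontal axis), with 95% exact binomial intervals, in 4 conditions, and the share for simulated frameless reads in upf1 + CHX (dashed line). At 50 or more reads 70.9% of the upf1 + CHX ORFs were called against 10.1% of frameless ones, while single reads were called in 89.2% of ORFs.

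By transcript, 769 XUTs (47.0%, 44.5 to 49.4) had a called ORF in WT, 1256 (76.7%, 74.6 to 78.8) in WT + CHX, 1102 (67.3%, 64.99 to 69.6) in upf1 and 1274 (77.8%, 75.7 to 79.8) in upf1 + CHX. XUTs with any read numbered 803, 1311, 1146 and 1328 in the same order. Nearly all of them had a called ORF, so these shares follow whether a XUT received a read. No frameless value was computed for XUTs, and the shares are no estimate of XUTs translated. With at least 10 reads, XUTs with a called ORF numbered 26, 356, 213 and 432. At that depth XUT1813 on the 2-micron plasmid had 13 of 20 ORFs called in at least 1 condition. XUT1511, which overlaps a long terminal repeat (LTR) whose copies can share reads and lies antisense to GAS2, a gene for a cell-wall glucanosyltransferase, had 8 of 25. XUT0602, antisense to DYN1 and YSR3, had 8 of 32. XUT0961, antisense to PDR3, a transcription factor of multidrug resistance, had 8 of 33, and XUT0815, antisense to RSB1, had 8 of 25. With no read minimum the 5 XUTs with most called ORFs were XUT0860 (antisense to GAL4 and GYP5), with 46 of 58, XUT0467 (CSS1) and XUT0925 (OPT2 and YPR195C) with 41 of 49 each, XUT1656 (PDR18) with 38 of 51 and XUT0793 (YOL153C) with 34 of 42.

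The 10 transcripts named by mean score over the 4 conditions all had an ORF at the ceiling of 1. They were XUT0046, XUT0050, XUT0056, XUT0115, XUT0134, XUT0189, XUT0326, XUT0449, XUT0456 and XUT0467, and these ORFs had 1 to 4 reads per condition. Ties were cut by identifier, so further XUTs may share that value. Among ORFs with at least 10 reads in each condition, an 18-nt ORF of XUT1813 on the 2-micron plasmid (1420 to 1437) led with a mean of 0.770. It was followed by a 42-nt ORF of XUT0567 antisense to MNN4 (chromosome 11, 66559 to 66600), with 0.659, and the 24-nt first ORF of XUT1036 beside ARF2 (chromosome 4, 217079 to 217102), with 0.527. MNN4 acts in the phosphorylation of cell-wall mannans, and ARF2 encodes an ADP-ribosylation factor.

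Loss of Upf1 in untreated cells was compared next. Of the 140 XUTs with enough reads, 85 had an ORF antisense to a gene, as did 5 of the 6 whose share of the reads was highest in upf1 relative to WT. The other was XUT1092 near RNH202 (3.74-fold, on 67 reads in upf1 and 4 in WT). XUT1612, antisense to YTP1 (chromosome 14, first to last ORF 205014 to 206635), had 191 reads in upf1 and 6 in WT, a 7.11-fold larger share (log2 2.83, 95% counting interval 1.68 to 4.29). The 2-micron plasmid, kept in the totals, held 25.4% of the compared reads in WT and 10.9% in upf1. Without it this ratio and those below would be smaller. XUT0195, antisense to UPS3, had a 4.91-fold larger share, on 88 reads in upf1 and 4 in WT. XUT1253, antisense to the cardiolipin deacylase gene CLD1, had a 4.19-fold larger share, on 75 and 4 reads. XUT0086, antisense to YCL049C, had a 3.87-fold larger one, on 104 and 6 reads. These larger shares were picked as the largest and divide by WT counts at or near the minimum of 4 reads, so their size is uncertain. Smaller shares were found for XUT1514 near SEI1 (0.180-fold), XUT1492 near FAR10 (0.232-fold), XUT1547 near GIS4 (0.271-fold) and XUT0957 near the ribosomal protein gene RPL19B (0.330-fold).

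XUT0741 lies antisense to ADH2, the alcohol dehydrogenase that oxidises ethanol (chromosome 13, 873057 to 874391). Over its non-overlapping ORFs it had 82 reads in upf1 against 4 in WT, a 4.58-fold larger share with the plasmid kept in the totals (log2 2.19, 95% counting interval 0.78 to 4.10). Most came from its first ORF, of 45 nt (873057 to 873101), 190 nt from ADH2, which held 3 reads in WT, 29 in WT + CHX, 45 in upf1 and 48 in upf1 + CHX. Its score was 0.577, 0.520, 0.465 and 0.929 in that order. A 285-nt ORF opposite the ADH2 CDS (873466 to 873750) held 1, 20, 25 and 33 reads and scored 1, 0.471, 0.256 and 0.195.

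Phase scores in untreated upf1 were lower than in WT, with a median difference of -0.128 (95% interval -0.152 to -0.090, 1502 ORFs). Frameless reads at the same counts gave -0.291. Of the 1956 ORFs with reads in WT, 1237 had a single read, where the frameless score is 1 and no score can lie above it, so score differences above the frameless expectation are given only for at least 10 reads. With at least 10 reads in both conditions the median was -0.063 (-0.104 to -0.033) over 57 ORFs of 36 XUTs, 41 of which were lower in upf1, and above the frameless expectation it was -0.030 (-0.071 to 0.031). The interval also included 0 over the 16 of them with counts within 1.5-fold (-0.048, -0.104 to 0.167) and over the 13 that overlapped no other listed ORF (-0.043, -0.104 to 0.159). Above the frameless expectation the latter was 0.028 (-0.085 to 0.186). The falls were led by the 42-nt ORF of XUT0567 antisense to MNN4, from 1 to 0.267, and included the last ORF of XUT0166 (chromosome 4, 513239 to 513328), from 0.635 to 0.239. ORFs antisense to YPL162C in XUT0869 (0.750 to 0.399), to ADH7 in XUT1022 (0.506 to 0.276) and to COX5B in XUT1341 (0.447 to 0.233) were also among them. COX5B encodes a subunit of cytochrome c oxidase. The remaining falls were in XUT1813, XUT0957 and XUT1639. Rises were led by a 27-nt ORF of XUT1511 (0.339 to 0.793) and a 33-nt ORF of XUT1813 (0.186 to 0.586). They included a 453-nt ORF of XUT0398 antisense to LSC2, a subunit of succinyl-CoA ligase (0.200 to 0.481), and ORFs of XUT0109, XUT1793, XUT0733, XUT1682 and XUT1722. Of these, only the falls in XUT0567 and XUT1639 and the rise in XUT1813 exceeded 95% of the differences that frameless reads give at the same counts. Of all 47 ORFs with 10 reads in both conditions and a call, 1 rose and 3 fell beyond that limit (8.5%). The named ORFs were picked as the largest changes, so this is no test of them.

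With CHX, scores were higher in upf1 than in WT among well covered ORFs. The median difference was 0.046 (0.025 to 0.069) over 686 ORFs with at least 10 reads in both, of which 402 were higher and 282 lower in upf1. It was 0.056 (0.028 to 0.079) over the 466 ORFs whose counts lay within 1.5-fold. Over all 3995 ORFs with reads in both, the setting fixed in advance, the median was 0, and 1072 ORFs had equal scores. Rises were led by first ORFs of XUT1130 near NOP16 (chromosome 5, 156388 to 156432), from 0 to 0.823, XUT0961 (0.154 to 0.895) and XUT0830 near SYC1 (0.212 to 0.917). They also included XUT0387 antisense to PBP1 (0 to 0.581) and ORFs of XUT1303, XUT0520, XUT1015 and XUT0001. Falls were led by a 216-nt ORF of XUT0033 (chromosome 2, 251533 to 251748), from 1 to 0.289, and XUT0066 near SUP45 (0.901 to 0.25). They included XUT1070 antisense to APC4 (0.764 to 0.217) and ORFs of XUT1441, XUT1053, XUT1034, XUT0618 and XUT0688. All 8 named rises and 8 named falls exceeded 95% of frameless differences, which is no test, since they were picked as the largest. Of all 592 ORFs with 10 reads in both conditions and a call, 42 rose and 33 fell beyond that limit (12.7%).

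By read share with CHX, XUT0824 near ORT1 was 4.76-fold higher in upf1 than in WT, XUT0340 antisense to VPS73 was 4.69-fold higher and XUT1700 antisense to RGS2, a regulator of G-protein signalling, was 4.20-fold higher. They had 6, 12 and 7 reads in WT + CHX and were picked as the largest. XUT0942 near UIP3 (0.282-fold) and XUT0372 near PPT1 (0.285-fold) had the smallest shares relative to WT.

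CHX was then compared with no treatment in WT. The 24-nt first ORF of XUT1036 went from 10 reads to 393, and the whole transcript took a 5.35-fold larger share (log2 2.42, 95% counting interval 1.66 to 3.30). XUT1253 antisense to CLD1 took a 7.31-fold larger share, on 4 reads in WT and 179 in WT + CHX. XUT1139 near RPL34A took a 4.41-fold larger one, on 5 and 135 reads. The ratio of XUT1253 divides by the same 4 WT reads as its ratio for upf1 against WT, so these ratios are not independent. XUT1639, which overlaps a Ty element whose copies can share reads, took 0.125-fold its share without CHX, and XUT1813 on the 2-micron plasmid 0.239-fold. The plasmid held 25.4% of the compared reads in WT and 6.55% in WT + CHX, and without it the other ratios would be smaller. Scores were lower with CHX by a median of -0.211 (-0.268 to -0.160, 1582 ORFs), against -0.315 for frameless reads at the same counts. With at least 10 reads in both, the median was -0.073 (-0.130 to -0.011) over 58 ORFs, and -0.027 (-0.068 to 0.021) above the frameless expectation. Falls were led by XUT0759 antisense to YNL134C (0.700 to 0.065), a 102-nt ORF of XUT0567 antisense to MNN4 (0.866 to 0.446) and XUT0869 antisense to YPL162C (0.750 to 0.365), with XUT1813, XUT1156, XUT0166, XUT0957 and XUT1639 after them. Rises were led by XUT1793 near AXL1 (0.304 to 0.668), XUT1577 antisense to FPY1 (0.077 to 0.340) and XUT0780 near YNR061C (0.451 to 0.663), with XUT1514, XUT1511, XUT1813, XUT0083 and XUT0468 after them. None of the 8 rises exceeded 95% of frameless differences, and of the falls those of XUT0759, XUT0567 and XUT0957 did. Of all 47 ORFs compared in this way, 0 rose and 3 fell beyond that limit (6.4%), and the named ones were picked as the largest.

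In upf1, the median score difference with CHX was 0 over 3562 ORFs and -0.00022 (-0.017 to 0.017) over the 451 with at least 10 reads in both, of which 224 were higher and 227 lower. Above the frameless expectation the latter was 0.020 (0.00023 to 0.035), an interval that barely excludes 0. It was 0.016 (-0.0055 to 0.041) with counts within 1.5-fold and 0.018 (-0.015 to 0.066) without overlapping ORFs, so no rise was established. Rises were led by XUT1591 (chromosome 13, 769706 to 769849), from 0.1 to 0.967, XUT0193 (0.167 to 0.923) and XUT0772 near ATO2 (0.224 to 0.975). They included XUT0281 antisense to GPP2, a glycerol-phosphate phosphatase (0.179 to 0.699), XUT1525 antisense to NGK1, XUT1782 antisense to CSR2, XUT1654 and XUT0618. Falls were led by XUT0756 near YGP1 (0.687 to 0.114) and XUT1590 near RPS10B (0.729 to 0.198). They included XUT1071 antisense to SWF1 (0.667 to 0.189), XUT1107 antisense to THI74 (0.577 to 0.129), XUT1465, XUT1577, XUT0599 and XUT1511. All of these exceeded 95% of frameless differences, again as the largest of many. Of all 387 ORFs compared in this way, 30 rose and 23 fell beyond that limit (13.7%). By read share, XUT0688 near RPL6A was 6.68-fold higher with CHX, XUT0156 antisense to GPR1 and PUS9 6.09-fold and XUT0333 antisense to COX4 5.07-fold. These XUTs had 5, 5 and 6 reads in upf1 without CHX, near the minimum of 4, and were picked from the largest.

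The CHX effect on the score in upf1 minus that in WT was 0.211 between the medians of all ORFs. It was 0.073 between those of ORFs with at least 10 reads in both, and 0.048 (95% bootstrap interval over ORFs -0.00073 to 0.090) above the frameless expectation. Among the 57 ORFs with at least 10 reads in all 4 conditions, the median per-ORF difference was 0.153 (0.090 to 0.219), above 0 in 41, and 0.130 (0.051 to 0.177) above the frameless expectation. These ORFs lay in 36 XUTs, and only 13 overlapped no other listed ORF. The others can share reads, so these intervals may be too narrow. Of the 58 WT ORFs with at least 10 reads, 11 lay on the 2-micron plasmid. No replicate test of this interaction was possible.

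The conditions shared many calls. All 4 conditions called 578 ORFs and 648 XUTs, and 18 ORFs and 19 XUTs with at least 10 reads. Of the 41 ORFs called in WT at that depth, 25 were also called in upf1, where independent lists would share 0.932, and 28 in WT + CHX, where they would share 1.52. Of the 517 in WT + CHX, 330 were called in upf1 + CHX, where independent lists would share 25.6. Both lists require 10 reads, which ORFs with many reads reach in every condition, while the independent values were taken over all 13941 ORFs. The excess was thus set by depth and shows no agreement in framing. Among the 57 ORFs with 10 reads in both, 31 were called in upf1 and 41 in WT. For WT + CHX and WT these were 34 and 41 of 58, and for upf1 + CHX and WT + CHX 491 and 431 of 686. With most of them called in each condition, many shared calls follow without agreement. In upf1 + CHX 185 called ORFs had scores within 0.05 of the threshold, and calls so close to it can switch by counting noise.

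Footprints were densest per nt in the first listed ORF of the XUTs. As a share of reads, ORFs of order 5 or later together held more than first ORFs in WT (34.0% against 27.1%) and upf1 (36.0% against 28.7%). They held less in WT + CHX (29.3% against 34.1%) and upf1 + CHX (28.4% against 34.8%). In the 1343 XUTs with at least 3 ORFs, those of the 2-micron plasmid left out, footprint density in the first ORF was 3.47-fold that of the later ORFs in WT (95% bootstrap interval 2.61 to 4.55), 4.81-fold (4.14 to 5.60) in WT + CHX, 3.75-fold (3.12 to 4.47) in upf1 and 4.97-fold (4.28 to 5.75) in upf1 + CHX. With CHX this ratio was 1.39-fold higher (1.13 to 1.72) in WT and 1.32-fold higher (1.19 to 1.48) in upf1, whereas upf1 and WT differed by 1.08-fold (0.904 to 1.30) without CHX. ORFs called with at least 10 reads had a mean relative order of 0.194, against 0.550 for the other ORFs of the same XUTs (permutation p = 1e-05, the smallest the permutations can give, across ORFs). Without a read minimum the means were 0.439 and 0.584 (permutation p = 1e-05). Both comparisons follow where the reads lie, since calls depend on having reads. In the 82 XUTs with both called and uncalled ORFs of at least 10 reads, the 171 called ORFs had a mean relative order of 0.242 and the 102 uncalled ones 0.404 (permutation p = 0.0001, the smallest those permutations can give, across ORFs). That comparison does not match depth, since ORFs with 10 reads in more conditions can be called in more of them. Among ORFs of the same XUT with 10 reads in as many conditions, 59 called ORFs had a mean relative order of 0.294 and 60 uncalled ones 0.415 (permutation p = 0.0148, adjusted p = 0.0389 over 9 tests at matched depth). Within 1 condition and the same class of read number, the means of called and uncalled ORFs were 0.202 and 0.353 in upf1 (adjusted p = 0.0126), 0.223 and 0.316 in upf1 + CHX (adjusted p = 0.0389) and 0.249 and 0.268 in WT + CHX (adjusted p = 0.584). With only the minimum of 10 reads in that condition they were 0.185 and 0.312 in upf1 (adjusted p = 0.009), 0.229 and 0.288 in upf1 + CHX (adjusted p = 0.0554) and 0.267 and 0.240, in the opposite direction, in WT + CHX (adjusted p = 0.584). WT had too few ORFs for either comparison. Only in upf1 was the position of called ORFs beyond that of the reads detected both ways, and the difference between conditions was not tested. None of these comparisons matched ORF length, and longer ORFs scored lower with at least 10 reads (Spearman's rho -0.404 in upf1). They therefore cannot separate position from ORF length.

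**Figure D2:**
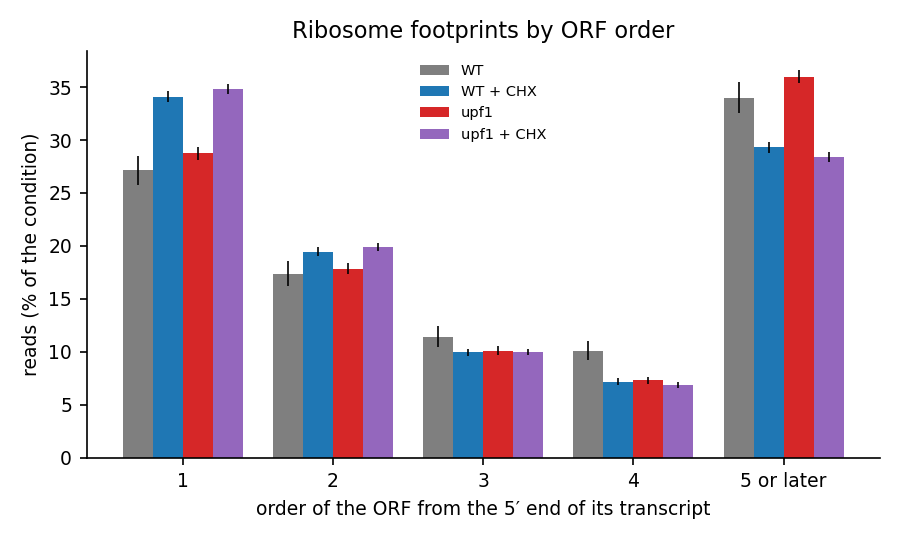
Share of the reads of each condition (vertical axis, percent, with 95% exact binomial intervals) by order of the ORF from the 5′ end (horizontal axis) in XUTs with at least 3 ORFs, without the 2-micron plasmid. First ORFs held 27.1% of these reads in WT, 28.7% in upf1, 34.1% in WT + CHX and 34.8% in upf1 + CHX, and 22.6%, 26.2%, 32.4% and 33.0% with the plasmid kept.

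Long ORFs held a smaller share of the reads with CHX. With the 2-micron plasmid left out, ORFs over 150 nt held 21.2% (20.05 to 22.5) of reads in WT and 13.6% (13.2 to 13.9) in WT + CHX, and 21.6% (21.1 to 22.2) in upf1 and 16.5% (16.2 to 16.9) in upf1 + CHX. ORFs of up to 30 nt held 11.3% (10.3 to 12.2) in WT and 15.4% (15.0 to 15.7) in WT + CHX. With the plasmid, whose 264-nt ORF alone held 716 of the WT reads, the long ORFs held 28.2% in WT, 15.5% in WT + CHX, 23.7% in upf1 and 17.8% in upf1 + CHX, and the short ones 10.6% in WT and 14.8% in WT + CHX. Longer ORFs scored lower, with Spearman's rho across ORFs of -0.064 in WT, -0.116 in WT + CHX, -0.183 in upf1 and -0.150 in upf1 + CHX, and -0.229, -0.366, -0.404 and -0.419 with at least 10 reads. Frameless scores are also higher in shorter ORFs. Above the frameless expectation, rho with at least 10 reads was -0.080 (95% bootstrap interval -0.381 to 0.224) in WT, -0.183 (-0.246 to -0.112) in WT + CHX, -0.255 (-0.336 to -0.171) in upf1 and -0.218 (-0.277 to -0.155) in upf1 + CHX. With no minimum it was 0.011 (-0.033 to 0.056) in WT, -0.040 (-0.070 to -0.0093) in WT + CHX, -0.0082 (-0.038 to 0.019) in upf1 and -0.028 (-0.056 to -0.0023) in upf1 + CHX, so no relation was detectable in WT and upf1. Those values include the ORFs with a single read, which cannot lie above the frameless score. The rho of read number and score was -0.569 to -0.644 across the conditions with no minimum, and -0.070 to -0.156 with at least 10 reads.

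All ORFs with a reference sequence start with ATG. An A at position -3, the favoured base of yeast start sites, preceded 29.8% of the 8069 ORFs called in any condition and 28.0% of the 5843 not called (adjusted p = 0.047, Fisher's exact test across ORFs). The difference missed the threshold against ORFs matched on length (adjusted p = 0.068). Of all listed ORFs, 5474 had no read in any condition and could not be called. Comparisons with ORFs not called therefore mainly set ORFs with reads against ORFs without reads. Among ORFs called with at least 10 reads the share with A at -3 was 35.5% (32.4 to 38.6, adjusted p = 5.25e-05). Among first ORFs it was 39.1% in those called with at least 10 reads and 27.2% in uncalled ones (adjusted p = 0.00199). ORFs with at least 10 reads that were not called had 36.2% (28.6 to 44.4), and no difference between called and uncalled ORFs was detectable at that depth (adjusted p = 0.856). G at position +4 was less frequent in ORFs called with at least 10 reads than in ORFs not called (19.5% against 24.3%, adjusted p = 0.0048), and among first ORFs (16.4% against 28.4%, adjusted p = 0.000404). Uncalled ORFs with at least 10 reads had 24.3% (17.8 to 32.0, adjusted p = 0.239). For neither base were called first ORFs compared with uncalled first ORFs of at least 10 reads. Median GC content was 37.3% in ORFs called with at least 10 reads, 38.4% in uncalled ORFs with at least 10 reads and 39.7% in ORFs not called.

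The antisense ORFs held a larger part of the footprints without Upf1. They held 27.9% (26.8 to 29.1) of reads in WT, 36.0% (35.5 to 36.5) in WT + CHX, 43.9% (43.3 to 44.5) in upf1 and 39.6% (39.1 to 40.04) in upf1 + CHX. These shares keep the 2-micron plasmid in the total, and its larger share in WT lowers the antisense share there. Per read in ORFs without a CDS, a measure that leaves the plasmid out, antisense reads were 0.607 in WT and 1.05 in upf1. This was a 1.73-fold difference (95% bootstrap interval 1.46 to 2.03). With CHX the difference between upf1 and WT was 1.18-fold (1.11 to 1.26). The ratio with CHX was 0.725 times that without it (0.655 to 0.803) in upf1 and 1.06 times (0.889 to 1.27) in WT. No rise with CHX in WT was thus detected once the plasmid was left out. The 2-micron plasmid, a multicopy plasmid of yeast, held 24.9% (23.8 to 26.02) of the reads in WT, 7.14% (6.88 to 7.41) in WT + CHX, 11.7% (11.3 to 12.1) in upf1 and 6.74% (6.51 to 6.98) in upf1 + CHX.

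**Figure D3:**
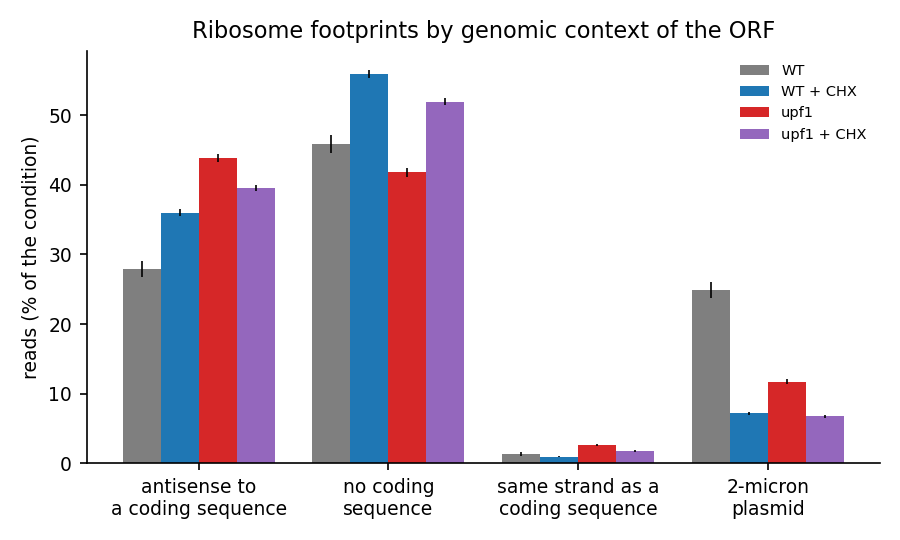
Share of the reads of each condition (vertical axis, percent, with 95% exact binomial intervals) in ORFs antisense to a coding sequence, without one, on the same strand as one, and on the 2-micron plasmid. Antisense ORFs ran from 27.9% in WT to 43.9% in upf1, and the plasmid from 24.9% in WT to 6.74% in upf1 + CHX. The plasmid is kept in the totals, which lowers the other shares most in WT.

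There were 4 XUTs that overlap annotated genes on their own strand. XUT0468 covers the pseudogene SDL1, and its 381-nt first ORF (chromosome 9, 29032 to 29412) held 42 reads in WT, 135 in WT + CHX, 396 in upf1 and 355 in upf1 + CHX. With the 2-micron plasmid kept in the totals, SDL1 reads made up a 2.12-fold larger share in upf1 than in WT (95% counting interval 1.54 to 2.97). With CHX the share was 2.09-fold larger (1.72 to 2.56). The pseudogene YOL153C (XUT1664) had a share ratio of 2.05 (0.883 to 5.82) without CHX and 2.77 (1.80 to 4.38) with it. The pseudogene YIR043C (XUT1354) had 0 reads in WT, a count that allows up to 3, and 17 in upf1, and its share ratio was 1.70 (0.823 to 3.71) with CHX. YGR016C-A (XUT1234) had ratios of 0.930 (0.373 to 2.77), on 6 reads in WT, and 1.03 (0.735 to 1.46) with CHX.

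The gene lists, matched through the gene on the opposite strand, had few members. Glycolysis and histones had 0. The list of ribosomal protein genes matched by name only RPP1, which encodes a subunit of RNase P and not a ribosomal protein, so it held no member. NMD targets had 1 (HAP4), with medians of -0.134 over 3 ORFs for upf1 against WT with CHX and 0.231 over 4 ORFs for CHX in upf1. Galactose genes had 5 members in 5 XUTs, with 8 reads in WT, 60 in WT + CHX, 121 in upf1 and 115 in upf1 + CHX. In XUT1479, antisense to the galactose permease gene GAL2, a 60-nt ORF (chromosome 12, 291611 to 291670) scored 0.441 in upf1 and 0.768 in upf1 + CHX, on 10 and 12 reads. The median of the galactose list for upf1 against WT without CHX was 0.184 over 6 ORFs, at percentile 98.9 of random lists, but none of the 6 had 10 reads in both conditions. It was 0 over 20 ORFs with CHX, at percentile 49.9. The sporulation list (NDT80, SPO11 and SPO13, 3 XUTs) had 21, 75, 128 and 157 reads in WT, WT + CHX, upf1 and upf1 + CHX. An ORF of XUT0418 antisense to SPO11, which makes the DNA breaks of meiotic recombination, scored 0.641 in WT + CHX and 0.191 in upf1 + CHX (chromosome 8, 63040 to 63120). ORFs antisense to the meiotic regulator NDT80 (XUT1304, 0.265 and 0.442) and to SPO13 (XUT1288, 0.254 and 0.211) were compared in the same conditions.

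Amino acid synthesis had 4 members, with XUT1678 antisense to ARG1 at 0.700 in WT + CHX and 0.573 in upf1 + CHX. Heat shock had 2, with XUT0104 antisense to HSP30 at 0.401 and 0.504. Cell cycle and mating (CLN1, CLN2 and FAR1) had a median difference of 0.161 for upf1 against WT with CHX over 9 ORFs, at percentile 99.2 of random lists, and of -0.625 over 4 ORFs without CHX, at percentile 11.2. For CHX in upf1 it was 0.084 over 7 ORFs, at percentile 97.5. Transporters had 6 members, with a median of -0.046 over 19 ORFs with CHX, at percentile 6.49, and of 0.087 over 4 ORFs for CHX in WT, at percentile 96.5. Phosphate genes had 3, with a median for upf1 against WT of -0.5 over 3 ORFs without CHX and of 0 over 5 ORFs with it, and of 0.228 over 5 ORFs for CHX in upf1. No ORF of the NMD, cell cycle, transporter and phosphate lists had 10 reads in both conditions of a contrast. The percentiles given include the most extreme of those computed. Others lay near the middle, such as 52.85 for heat shock (8 ORFs) and 48.4 for sporulation (11 ORFs), for upf1 against WT with CHX. Random lists drew single ORFs, while ORFs of a list can share a XUT, as in the cell cycle list with 4 XUTs. These percentiles describe the merged libraries and are not tests between conditions.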

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

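The tests of the first-ORF ratio without the 20 most-read transcripts, of the antisense share over non-overlapping ORFs, and of the difference between the CHX ratios of upf1 and WT, as well as the 10-read minimum, were chosen after the results were seen.

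The score difference between upf1 and WT had opposite signs without and with CHX. Among ORFs with at least 10 reads in both conditions the median was -0.063 without CHX (57 ORFs) and 0.046 with it (686 ORFs). Above the frameless expectation these were -0.030 (-0.071 to 0.031) and 0.066 (0.044 to 0.081). Only the difference with CHX was thus left beyond that background, which models read number and ORF length but not piled-up reads. The difference between these contrasts was not tested across replicates, which the table merges. The ORFs with 10 reads in all conditions gave a per-ORF difference of CHX effects of 0.153, and 0.130 (0.051 to 0.177) above the frameless expectation. Most of these ORFs overlapped another listed ORF and can share reads, so that interval may be too narrow.

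The antisense to no-CDS read ratio moved with CHX by 0.725-fold in upf1 and by 1.06-fold in WT. The ratio of those values was 0.684 (95% bootstrap interval over transcripts 0.579 to 0.811), which compares these merged libraries and not cultures. In the pooled scores, which no comparison used, 628 ORFs were called with at least 10 reads that were not called at that depth in any single condition. They lay in 431 XUTs, of which 224 had another ORF called with at least 10 reads in a condition.

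More ORFs were called in upf1 and with CHX than in WT, from 4356 to 5012 against 1746. Thinning each condition to the 5897 reads of WT, and applying the share of calls WT had at each read number, left 1971 calls in upf1 + CHX, the lowest, with 2018 in WT + CHX and 2019 in upf1. Read number thus brought the difference down to 1.13 to 1.16 times WT. Every draw stayed above the WT count, the lowest being 1906 in upf1 + CHX, 1946 in WT + CHX and 1965 in upf1. The lowest draw in upf1 + CHX fell within the margin over WT set in advance for this test. Whether read number was the whole cause therefore stayed undecided. WT had 33.7% of its reads in its 20 most-read ORFs, against 13.1% to 18.8% elsewhere. Without the 20 ORFs with most pooled reads, thinning gave 1769 in upf1 + CHX against 1728 in WT, so read number and a few ORFs together may account for the difference in the number of ORFs reached by reads. Both tests give every condition the call rate of WT, so they leave out any effect on framing.

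The larger antisense share in untreated upf1 (1.73-fold relative to ORFs without a CDS) was not removed by any technical test run. Leaving out the 50 most-read ORFs gave 1.48 (1.29 to 1.71). Non-overlapping ORFs gave 1.72 (1.45 to 2.00). Leaving out ORFs within 500 nt of a same-strand CDS, where footprints of coding mRNAs could spill over, gave 1.68 (1.42 to 2.01), after a first run that left out only those ending upstream of one. That antisense XUTs are more sensitive to Upf1 than other XUTs is a hypothesis that was not tested, and variation between cultures and RNA levels, not analysed here, stay open.

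The rise of first ORFs with CHX in upf1 (1.32-fold) was 1.37 (1.26 to 1.49) without the 20 most-read XUTs and 1.31 (1.16 to 1.49) over non-overlapping ORFs. Among ORFs over 60 nt it was 1.21 (1.06 to 1.40), and in WT 1.21 (0.927 to 1.61), an interval that includes 1. Few transcripts, shared reads and short ORFs therefore do not account for it fully in upf1. CHX added before harvest is known to let initiation go on while elongation stops, which is a candidate explanation that was not tested, and differences between cultures stay open.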

How the results depend on the processing

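No paired analysis was possible because the table holds 1 merged value per condition. For the same reason leaving out replicates, a replicate block, DESeq2, the filter and the pseudocount were not run. All settings with a read minimum for transcripts, score differences, overlap, position, sequence context and length, the non-overlapping sets and the frameless expectation, were chosen after seeing the data. Of 156 alternative values, 98 stayed close to the main value, 51 moved, 1 lost its call and 6 reversed. All 40 alternative thresholds kept the ORF and transcript counts within 1.5 times, as did 12 of 16 minimum lengths. The thresholds were varied with no read minimum, where 57.8% (upf1 + CHX) to 81.7% (WT) of the called ORFs had 1 or 2 reads. By the inferred formula such calls score at or above every threshold tried, so these counts could respond little. No alternative threshold was run with at least 10 reads, so how far those counts depend on it was not tested.

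The counts of called ORFs depended on reads. In WT, WT + CHX, upf1 and upf1 + CHX, 10 reads left 41, 517, 317 and 689 ORFs and 26, 356, 213 and 432 transcripts. A minimum of 30 reads left 15, 118, 77 and 184 ORFs and 8, 92, 58 and 139 transcripts. ORFs of at least 60 nt numbered 1082, 2474, 2415 and 2679, and 1 ORF per transcript gave 576, 1116, 964 and 1147. ORFs called in all conditions went from 578 to 382 and 329 at thresholds of 0.43 and 0.5, and to 18 with 10 reads.

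The score differences of upf1 against WT and of CHX in WT turned to 0.529 and 0.5 with missing scores set to 0, by construction, since ORFs without reads in WT then enter as 0. They turned to 0.010 and 0.036 as scores above the frameless expectation, which decides nothing, since most ORFs in WT had 1 read and no score above the frameless one is possible there. Among ORFs called in both they were -0.061 and -0.134, with 10 reads in both -0.063 and -0.073, and with matched counts -0.048 (16 ORFs) and -0.140 (8 ORFs). For upf1 against WT with CHX, 10 reads gave 0.046 and matched counts 0.056. For CHX in upf1 they gave -0.00022 and 0.0080, on either side of 0. The difference of CHX effects was 0.073 with 10 reads in both and 0.153 with 10 reads in all conditions, and above the frameless expectation it was -0.036 over all ORFs, a reversal with the same fault and no evidence of a reversed effect, 0.048 with 10 reads in both and 0.130 with 10 reads in all. The rho of length and score with 10 reads was -0.229, -0.366, -0.404 and -0.419 in the order above. Above the frameless expectation it was 0.011 (a reversal, with an interval from -0.033 to 0.056), -0.040, -0.0082 (-0.038 to 0.019) and -0.028 with no minimum, and -0.183, -0.255 and -0.218 with 10 reads in the last 3 conditions. The odds ratio of an A at -3 was 1.09 (adjusted p = 0.068) against length-matched ORFs. It was 1.42 with 10 reads against ORFs not called, most of which had no reads. For the other changes the cause was not tested. The position of called ORFs kept its direction under every threshold, in nt, with 10 reads and against uncalled ORFs with 10 reads, and its p was the smallest the permutations can give in each, which shows nothing on how its strength varied. Against uncalled ORFs with 10 reads in as many conditions it kept its direction (permutation p = 0.0148), with ORF length not matched. The thresholds were varied with no read minimum here too, so most calls could not respond to them. The ratios of antisense reads stayed within their intervals. Depth limits WT most, with 58 ORFs of 10 or more reads.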

Other observations

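The test of all XUTs and of the antisense set with CHX was written before its result, and the relations without CHX and in XUTs without a CDS were added beside it. With 1 ORF taken per XUT, the most-read ORFs outside the 2-micron plasmid were mostly longer than the upper quartile of 84 nt. A 234-nt ORF of XUT0957 near RPL19B held 940 pooled reads and the 381-nt first ORF of XUT0468 held 937. The 126-nt first ORF of XUT1722 (chromosome 15, 969771 to 969896) held 816, with scores of 0.298 in WT and 0.407 in upf1 + CHX. The 24-nt first ORF of XUT1036, 5 nt from ARF2, was a short one, with 735. Ty elements and long terminal repeats overlapped 340 ORFs in 49 XUTs on the same strand, and their reads can come from other copies. The 264-nt ORF of XUT1813 on the 2-micron plasmid held 3900 pooled reads, the most of any ORF.

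A hypothesis written before its test, from general knowledge of NMD, was that XUTs with more RNA downstream of their most-read ORF gain read share in upf1, since long RNA after a stop codon favours NMD. The distance from the most-read ORF to the last listed ORF stood in for that length. With CHX, Spearman's rho across 631 XUTs, without the 2-micron plasmid, was 0.271 (95% bootstrap interval 0.198 to 0.345; Pearson's r 0.188; permutation p = 1e-05, the smallest the permutations can give, adjusted 1.5e-05 over 6 relations). Without CHX it was 0.273 over 267 XUTs (adjusted p = 1.5e-05), 0.381 among the 143 whose most-read ORF had no CDS opposite and 0.138 (-0.052 to 0.303, permutation p = 0.129, adjusted p = 0.129) among the 121 with an antisense one. Among XUTs whose most-read ORF had no CDS opposite, rho was 0.323 with CHX (363 XUTs). Among those with an antisense most-read ORF it was 0.110 (-0.013 to 0.224; 264 XUTs; permutation p = 0.0755, adjusted p = 0.091), and the difference between the classes was not tested. The prediction asked for the relation in both sets, so it was met only in part, and length of the XUT, RNA level and class may each contribute. XUTs are not independent replicates.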
